A study of Homo sapiens with 40 samples.

How the data were processed

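Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 28 libraries of human monocyte-derived macrophages and 12 libraries of human monocytes. Each library came with 1 peak list. The authors deposited the lists as positions only: each line gives a chromosome, a start and an end, a constant in place of a score, and no read count. Per the submitters' processing notes, reads were handled with CASAVA, FastQC and Bowtie2 and the build was hg19; versions and settings were not given in the sources used here. Per the file headers, the peaks came from HOMER findPeaks in a mode that gives peaks of varying width, with the header names shifted against the columns. The peak threshold, any background library and any shift of reads for the transposase offset were not given in the sources used here. Peaks were called in each library separately, so a missing peak can mean closed chromatin or too few reads.

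The positions were set beside gene positions of GRCh38, the only annotation used here: on 15 of 22 autosomes peaks lay past the last GRCh38 gene. Open chromatin can lie past the last gene in either build, so this does not settle the build. The positions were kept as hg19 on the submitters' notes, and none was converted. No hg19 annotation or genome sequence was used here. The planned shares over gene lists and the planned motif counts were therefore not run, and regions are named by hg19 position, counted from 1, instead of by gene. The rule for named regions, for this case, was the 5 regions of smallest p for each treatment and direction. Only autosomes were analysed.

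Groups were taken from the sample titles read with the treatment protocol. Among macrophages, N is untreated, L received LPS, T TNF, IFN interferon alpha (IFNA), and the joined codes received both or all of these. TNF was given at 10 ng/ml and IFNA at 25 ng/ml for 24 h, and LPS at 10 ng/ml for 3 h. N and L have 5 libraries each and T, TL, IFN, IFN_L, IFN_T and IFN_TL 3 each. Among monocytes, Mono_N and Mono_L are the libraries without and with LPS, and SLE_N and SLE_L those labelled SLE; each has 3. The labels do not tie replicates to separate donors, so p-values measure the spread between these libraries, which may in part be technical.

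Peaks of all 40 lists that overlapped by at least 1 bp were merged into 384606 regions of median width 765 bp. A library held a region where at least 1 of its peaks overlapped it by at least 1 bp. Of these regions, 125438 were held by 1 library and 25849 by all 40. Sequencing depth is unknown from the lists. List length stands in for it, and it varied from 43136 to 172711 autosomal peaks, so a longer list holds more of any set of regions.

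For each of LPS, TNF and IFNA, 175729 regions with a peak in at least 3 macrophage libraries were tested with a two-sided exact conditional test of peak presence, stratified by the other treatments. Each library was weighted by its odds of holding a peak among regions found in as many libraries. Regions with a Benjamini-Hochberg adjusted p under 0.05 were called gained or lost. Sets of regions were compared between libraries by an excess share: the percentage of the set with a peak in a library minus the percentage among regions found in the same number of the 40 libraries. This excess cannot fall below minus that matched percentage, which is small in short lists, so list length still bounds it. The monocyte LPS set held regions with a peak in at least 5 of the 6 monocyte libraries with LPS and at most 1 of the 6 without; the lost set was its mirror. Differences in excess share were tested by two-sided permutation of labels within strata, exactly up to 100000 arrangements and otherwise with 100000 draws. With 3 against 3 libraries the smallest p is 0.1, with 5 against 3 it is 0.0179, with 5 against 5 it is 0.00794, and with 2 strata of monocytes it is 0.005. For pairs of groups, regions with a peak in every library of one and in none of the other were counted and set beside the same count in other splits of those libraries.

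The tests were run on simulated data before use. With 200 regions planted in each direction at 90% against 10% presence, the LPS test found 118 gained and 184 lost among 159853 regions, the TNF test 190 and 87 among 159735, and the IFNA test 167 and 148 among 159865. False calls numbered 1, 2 and 4, and data without planted effects gave 0 calls. Gains and losses were thus not found equally well, and the reason was not tested. Planted regions had the same probability of a peak in short and long lists, whereas short real lists hold fewer peaks. These recoveries may therefore not carry over to the real lists. The simulation drew each library independently, whereas same-numbered libraries of some real groups deviated together (T and TL, mean correlation 0.475). Other splits of the real libraries gave up to 86 TNF gained and 159 IFNA lost calls. The simulated false calls may therefore understate those in the real data.

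The alternatives fixed before the data were examined were an unweighted test, the replicate number as a block, a minimum of 6 libraries, peaks covering at least 50% of the region, windows of 500 bp, limma on presence with the log2 number of peaks as covariate, shares without matching, and leaving out each library. Equal-length lists were planned only for files with scores. The line order was used in their place after seeing the data: in 40 of 40 lists the share of peaks also found in other libraries fell steadily from the first to the last lines, so the first 43136 autosomal lines of each list were kept. Omission of the 4 shortest lists and of the IFN_TL group was also added after seeing the data. No 2 libraries were duplicates; the highest Jaccard index of regions was 0.80, between T and TL replicate 3. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and limma 3.58.1.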

Results

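The 40 peak lists covered 8 groups of macrophages, which carried every combination of TNF, IFNA and LPS, and 4 groups of monocytes. Macrophages here are cells matured in culture from blood monocytes. TNF is an inflammatory cytokine, IFNA a type I interferon, and LPS a bacterial cell wall component that triggers Toll-like receptor 4. Lists held 114779 ± 25624 peaks in N (SD, n = 5) and 125193 ± 33884 in L (SD, n = 5). The groups with TNF and no IFNA had the shortest lists, 76660 ± 30087 in T and 75597 ± 25564 in TL (SD, n = 3 each), and IFN_TL had 123263 ± 4361 (SD, n = 3). Among monocytes the lists held 93130 ± 21170 peaks in Mono_N and 137592 ± 39024 in SLE_N (SD, n = 3 each). List length did not differ by treatment beyond the spread between libraries: with LPS it was 1.16 times that without (permutation p = 0.211), with TNF 0.812 times (p = 0.0859) and with IFNA 1.08 times (p = 0.54). In monocytes the ratio of SLE to other libraries was 1.31 (exact permutation p = 0.105).

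**Figure D1:**
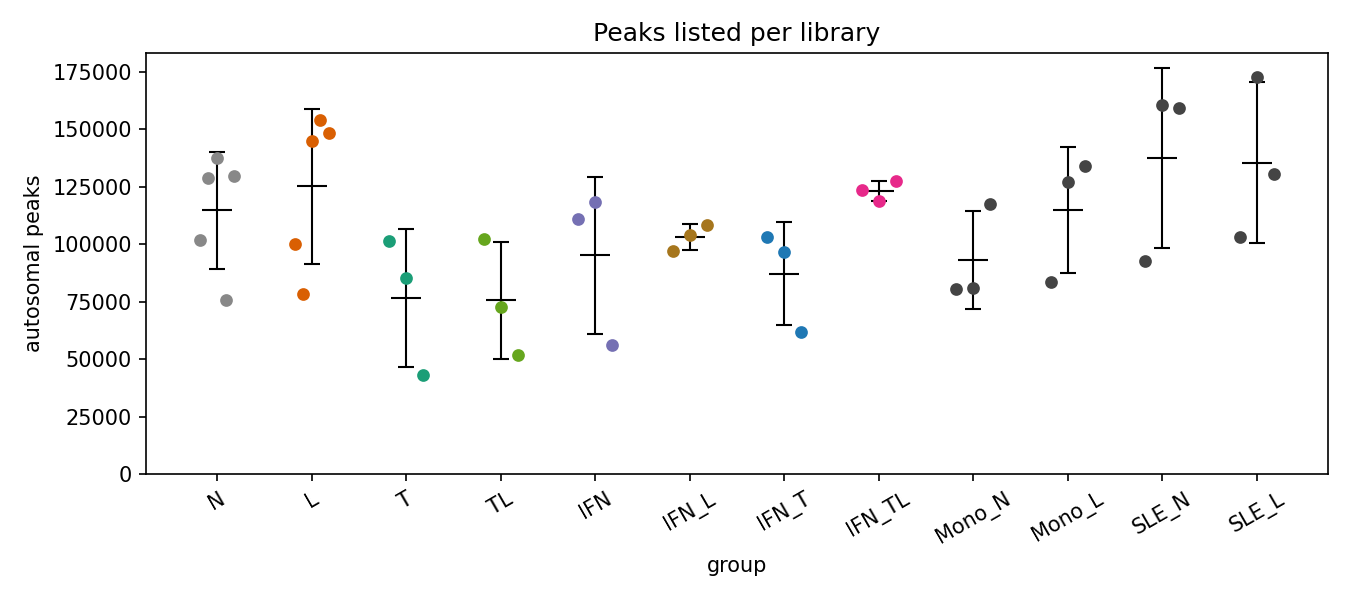
Autosomal peaks per library (y axis, linear) for the 12 groups (x axis); points are libraries, horizontal marks means and bars 1 SD. The lists ran from 43136 peaks in a T library to 172711 in an SLE_L library, and the 3 IFN_TL lists lay between 118818 and 127535.

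The first comparison asked which regions of macrophage chromatin opened or closed within 3 h of LPS, whatever the pretreatment. LPS went with 243 gained and 453 lost regions. Gained regions had a peak in 83.8% of library and region pairs with LPS and 10.1% without, and lost regions in 7.40% and 66.9%. The clearest gain lay on chromosome 10 from 71920794 to 71924363, with a peak in 14 of 14 LPS libraries and 1 of 14 others (adjusted p = 0.0156, stratified exact test). A region on chromosome 3 from 72994307 to 72995407 had a peak in 14 of 14 and 1 of 14, and in monocytes in 3 of 3 Mono_L and 3 of 3 SLE_L against 1 of 3 Mono_N and 1 of 3 SLE_N libraries. On chromosome 2 from 102374271 to 102376607 a peak was listed in 13 of 14 LPS libraries and in 0 of 14 others. The clearest loss lay on chromosome 12 from 26531306 to 26532928, with a peak in 1 of 14 LPS libraries and 12 of 14 others (adjusted p = 0.0156, stratified exact test). On chromosome 1 from 246368296 to 246369762 the peak was listed in 1 of 14 and 12 of 14 libraries. The gained regions were spread over all 22 autosomes, and no window of 1 Mb held more of them than chance after adjustment (lowest adjusted p = 0.0729, chromosome 14 from 103000001 to 104000000).

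The LPS counts varied widely between settings. Single omissions gave 39 gained regions without IFN replicate 1, and 32 or 689 lost ones without L replicate 3 or T replicate 3. With the replicate number as a block 0 and 0 were called, with 3812 and 7914 at an unadjusted p under 0.05. That block sets 1 library with LPS against 1 without in each stratum, which leaves 16384 arrangements and limits how small p can become. With 175729 regions tested, 0 calls there do not show that changes were absent. The unweighted exact test called 0 gained and 0 lost regions, with 7236 and 3430 at an unadjusted p under 0.05, while limma with the number of peaks as covariate called 1638 and 1396, equal-length lists gave 513 and 751, and without IFN_TL the weighted test called 74 and 77. The simulated data put the recovery of LPS gains below that of losses, 118 against 184 of 200, so the larger number lost is not a measured difference in frequency.

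**Figure D2:**
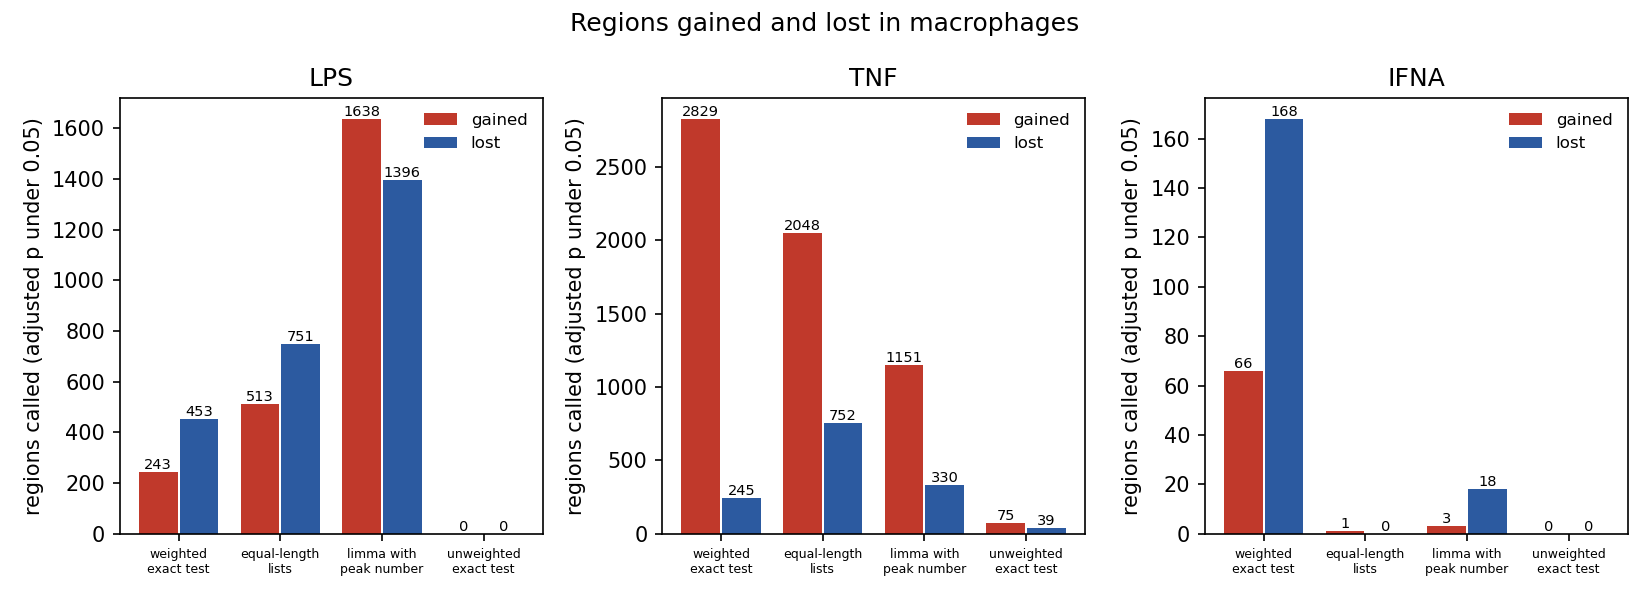
Regions called gained (red) and lost (blue) at an adjusted p under 0.05 (y axis, linear, scaled separately in each panel) for LPS, TNF and IFNA under 4 settings (x axis). The weighted test, equal-length lists and limma allow for list length, and the unweighted test does not. In that order TNF gained regions numbered 2829, 2048, 1151 and 75, whereas IFNA calls fell from 66 and 168 to 3 and 18 or fewer under the other 3 settings.

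The second comparison asked how 24 h of TNF changed the same chromatin, and it gave the most calls in the main test, though not with limma. TNF went with 2829 gained and 245 lost regions. Gained regions had a peak in 71.1% of library and region pairs with TNF and 22.1% without, and lost regions in 15.4% and 82.2%. At 5 gained regions the separation was complete, with a peak in 12 of 12 TNF libraries and 0 of 16 others (adjusted p = 3.35e-06, stratified exact test). They lay on chromosome 5 from 96228868 to 96229696, chromosome 6 from 2157234 to 2158477, chromosome 7 from 76108826 to 76110697, chromosome 14 from 89762670 to 89763337 and chromosome 15 from 44946880 to 44947790. A region lost with TNF lay on chromosome 3 from 116848425 to 116850504, with a peak in 0 of 12 TNF libraries and 16 of 16 others (adjusted p = 0.000371, stratified exact test). On chromosome 3 from 25790037 to 25792001 a peak was listed in 0 of 12 and 15 of 16 libraries. The lost region on chromosome 20 from 57915355 to 57921006 had a peak in 3 of 3 IFN_TL libraries, although T held it in 1 of 3 and TL and IFN_T in 0 of 3.

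Regions gained with TNF clustered along the genome. Of 2731 windows of 1 Mb, 14 held more of them than chance after adjustment. The leading window, on chromosome 3 from 59000001 to 60000000, held 9 gained among 64 tested regions where 1.03 were expected (adjusted p = 0.00243, exact test). A window on chromosome 8 from 134000001 to 135000000 held 13 of 163 where 2.62 were expected (adjusted p = 0.00342, exact test). Neighbouring regions are not independent, so these p-values describe clustering and not separate events. Regions gained with TNF also overlapped the monocyte LPS set, which comes from other libraries: 307 were shared where 43.8 were expected of independent lists (adjusted p = 6.03e-158, Fisher's exact test over regions, which are not independent replicates). Tested over libraries, the excess share of the regions gained with TNF differed by 6.04 points between monocytes with and without LPS, which did not pass (exact permutation p = 0.405).

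More gained than lost regions passed adjustment in each setting tried, and the size varied. Equal-length lists gave 2048 gained and 752 lost regions, limma 1151 and 330, the unweighted test 75 and 39 (4130 and 7520 at an unadjusted p under 0.05, where losses led), the replicate number as a block 489 and 0 (5381 and 2982 unadjusted), and the test without the 4 shortest lists 1253 and 91. In simulated data 190 of 200 gains and 87 of 200 losses with TNF were found, so there the test found gains more often than losses. The planted shares did not vary with list length, so the size of that imbalance in the real lists is not known.

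The third comparison asked what 24 h of IFNA did with or without TNF. IFNA went with 66 gained and 168 lost regions. Gained regions had a peak in 69.7% of library and region pairs with IFNA and 15.7% without, and lost regions in 6.15% and 47.5%. The clearest gain lay on chromosome 4 from 96527746 to 96528481, with a peak in 3 of 3 IFN and 3 of 3 IFN_L libraries, 1 of 3 IFN_T, 0 of 3 IFN_TL and none of the 16 libraries without IFNA (adjusted p = 0.0078, stratified exact test). The gain on chromosome 18 from 26092101 to 26092950 was held by 9 of 12 libraries with IFNA and 1 of 16 without. Of the lost regions, 4 of the 5 named ones had a peak in all 3 T and all 3 TL libraries and in no other macrophage library (adjusted p = 0.00566, stratified exact test). They lay on chromosome 1 from 67790201 to 67790987, chromosome 2 from 7642382 to 7643086 and from 106462183 to 106463163, and chromosome 4 from 74466345 to 74467311. Over the 168 lost regions the share with a peak was 82.5% ± 20.6 in T and 96.8% ± 2.94 in TL (SD, n = 3 each), and 12.9% ± 12.6 in IFN_T and 1.79% ± 0.595 in IFN_TL (SD, n = 3 each). In N it was 16.9% ± 4.49 (SD, n = 5). Of these regions 135 were also called gained with TNF, where 2.7 were expected of independent lists; both lists come from the same 28 libraries, which by itself can raise the overlap.

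The IFNA calls held in some settings and were lost in others. With at least 6 libraries 73 gained and 152 lost regions were called, of which 62 and 130 were among the main calls, and with peaks covering at least 50% of the region 21 and 143, of which 12 and 111 were. The unweighted exact test called 0 gained and 0 lost regions (5915 and 1998 at an unadjusted p under 0.05), limma called 3 and 18, equal-length lists gave 1 and 0, the replicate number as a block 0 and 27 (2736 and 3964 unadjusted), and 0 and 0 were called without TL replicate 3 (8892 and 4112 unadjusted), without the 4 shortest lists or without the IFN_TL group.

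**Figure D3:**
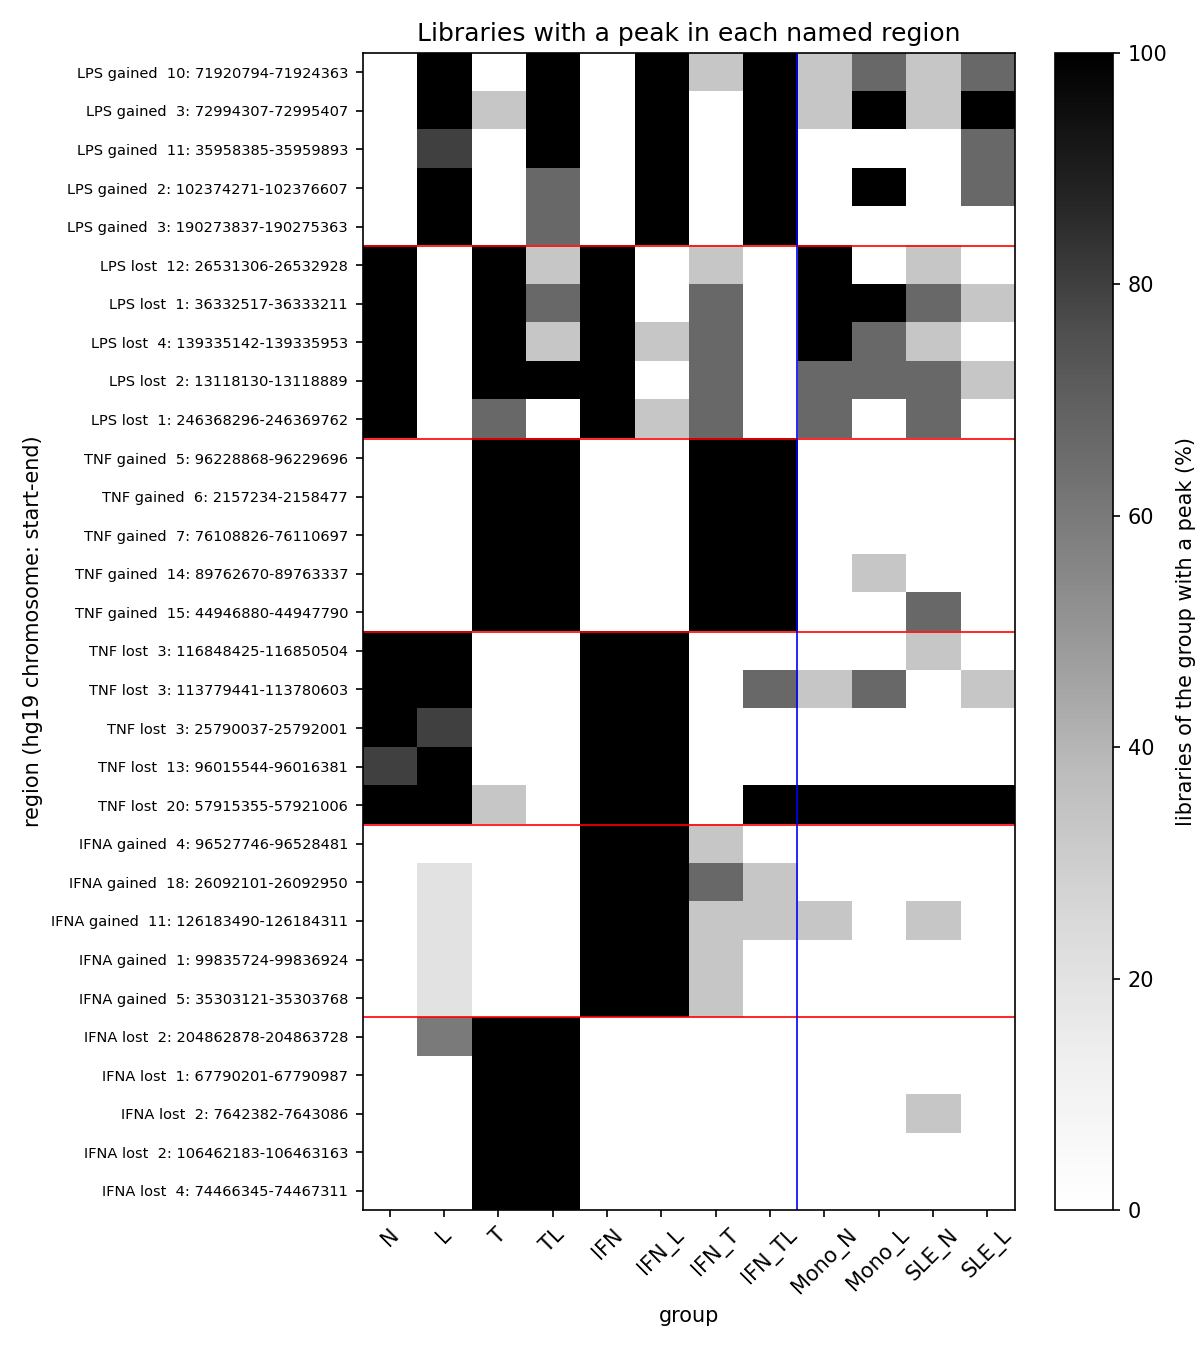
Share of the libraries of each group (x axis) with a peak, from 0% (white) to 100% (black), in the 30 named regions (y axis, hg19 positions); red lines separate treatments and directions, and the blue line separates macrophages from monocytes. The 5 regions gained with TNF were held by 12 of 12 TNF libraries and 0 of 16 other macrophage libraries.

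The fourth comparison asked whether macrophages treated first with TNF, or with TNF and IFNA, still responded to LPS. It used 3045 regions gained with LPS in monocytes, which are chosen without any macrophage library. In naive macrophages the excess share of this set rose with LPS, from -25.6 ± 6.88 points in N to 5.72 ± 12.7 in L (SD, n = 5 each), a difference of 31.4 points (exact permutation p = 0.00794, the smallest possible). With the replicate number as a block it did not pass (exact permutation p = 0.0625, the smallest the block allows). T stood at 5.01 ± 3.75 points (SD, n = 3), 30.7 above N (exact permutation p = 0.0179, the smallest possible). The matched percentage, which bounds the excess from below, was 4.34% in T replicate 3 but 24.5% to 62.5% in N. T replicates 1 and 2, with 43.9% and 31.4%, stood at 2.48 and 3.23 points. N replicates 1 and 4, with 38.9% and 24.5%, stood at -21.8 and -15.4. How far the bound shaped the difference was not tested. In plain shares, which follow list length, the set was held by 22.2% ± 9.02 in N, 56.7% ± 13.5 in L (SD, n = 5 each) and 31.6% ± 16.6 in T (SD, n = 3), so the shift with TNF depended on the matching. IFN stayed at -17.8 ± 7.56 points (SD, n = 3), and its difference from N of 7.80 was within the spread (exact permutation p = 0.196). After IFNA alone, IFN_L stood 30.8 points above IFN, which did not pass the test (exact permutation p = 0.1, the smallest possible). This difference departed from the naive one by -0.53 points (exact permutation p = 0.962).

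After TNF, with or without IFNA, the response to LPS over these gained regions did not pass the test. TL exceeded T by 7.76 points (exact permutation p = 0.2), and IFN_TL exceeded IFN_T by 0.27 points (exact permutation p = 0.9). With 3 against 3 libraries neither could go below 0.1. In plain shares, which follow list length, the set was held by 37.2% ± 22.9 in IFN_T and 59.5% ± 3.08 in IFN_TL (SD, n = 3 each). For T and TL the plain shares were 31.6% ± 16.6 and 38.9% ± 21.7 (SD, n = 3 each). TL lay above T in each of the 3 same-numbered pairs, at 15.8 against 2.48, 9.08 against 3.23 and 13.4 against 9.32 points. Over the 622 regions lost with LPS in monocytes IFN_TL stood at -43.6 ± 2.03 points and IFN_T at 10.4 ± 14.5 (SD, n = 3 each), a difference of -54.0 (exact permutation p = 0.1, the smallest possible). IFN_TL also stood -57.9 points from TL (exact permutation p = 0.1, the smallest possible). Same-numbered IFN_TL libraries deviated with those of the other TNF or IFNA groups at a mean correlation of at most 0.07. N libraries did so at no more than 0.024, so a low value is not particular to IFN_TL. A batch of the IFN_TL group cannot be told apart from a response to LPS here. On the same set TL differed from T by -4.55 points (exact permutation p = 0.6) and L from N by -30.8 (exact permutation p = 0.0317). The difference after TNF and IFNA departed from that after TNF by -49.5 points, which did not pass (exact permutation p = 0.09). Over the 3045 gained regions the response after TNF was lower than the naive one by a difference of -23.6 points, which did not pass the exact permutation test (p = 0.107). With equal-length lists and with peaks covering at least 50% of a region, the monocyte set was chosen anew, so its regions were not these 3045. Over the set from equal-length lists the difference was -31.1 points and passed the test (exact permutation p = 0.000319). Over the set from covering peaks it was -15.8 points and also passed (exact permutation p = 0.0153). IFNA together with TNF changed the LPS response by -7.49 points against TNF alone (exact permutation p = 0.085). That direction turned with unmatched shares over the same regions (15.0). It also turned over the sets chosen anew with covering peaks (13.9) and with equal-length lists (24.5), so no direction can be given.

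**Figure D4:**
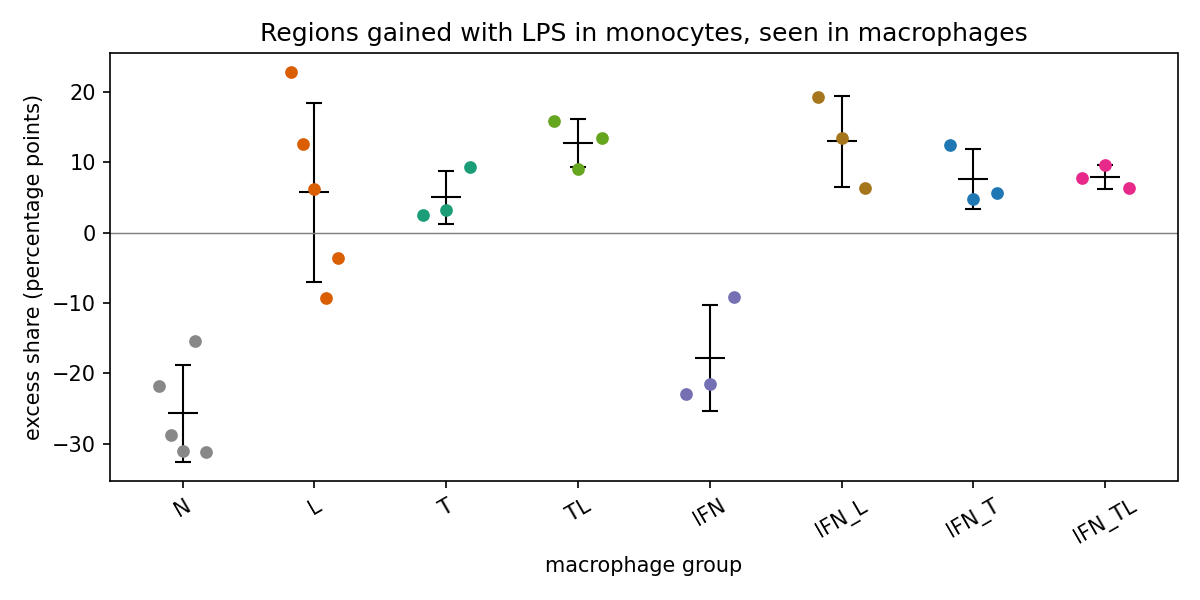
Excess share in percentage points (y axis) of the 3045 regions gained with LPS in monocytes, for each macrophage library by group (x axis); points are libraries, horizontal marks means and bars 1 SD, and the grey line marks 0. All 5 N and 3 IFN libraries lay below 0, and all libraries of T, TL, IFN_T and IFN_TL lay above it.

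The fifth comparison set macrophages beside monocytes. The regions gained with LPS in macrophages also rose with LPS in monocytes. Their share with a peak was 6.72% ± 4.51 in Mono_N and 64.3% ± 1.04 in Mono_L, and 11.8% ± 4.63 in SLE_N and 63.6% ± 1.66 in SLE_L (SD, n = 3 each). The excess share rose by 40.7 points (exact permutation p = 0.005, the smallest possible; adjusted p = 0.0283 over 34 tests of sets). Region by region, 100 of the 243 were also in the monocyte LPS set, where 3.76 were expected of independent lists. Fisher's exact test over regions, which are not independent replicates, gave an adjusted p = 2.72e-112. This expectation, like those of the other overlaps, counts all tested regions. Those held by all 40 libraries can enter neither set, so it is too low. Regions lost with LPS in macrophages moved the other way in monocytes with LPS, by -37.1 points (exact permutation p = 0.005, the smallest possible; adjusted p = 0.0283), and 26 of 453 were in the monocyte set of lost regions where 1.51 were expected.

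The sixth comparison asked whether SLE monocytes, those labelled with systemic lupus erythematosus, held more of the regions that the cytokines opened in macrophages. No difference was detected. Over the 66 regions gained with IFNA the excess share differed by -9.59 points between SLE and other monocytes (exact permutation p = 0.37). This pools 1.43 points without LPS and -20.6 with LPS (exact permutation p = 0.2 for the latter). Plain shares were 31.3% ± 14.4 in SLE_N against 13.1% ± 2.31 in Mono_N (SD, n = 3 each). With LPS they were 13.6% ± 4.01 in SLE_L against 27.8% ± 9.13 in Mono_L (SD, n = 3 each). Over the 2829 regions gained with TNF the excess share differed by -4.65 points (exact permutation p = 0.51). The response of the LPS gained regions was 43.7 points in SLE and 37.6 points in other monocytes, and the difference between these was not tested. Regions lost with LPS in macrophages were less often held by SLE monocytes, with a difference of -33.7 points (exact permutation p = 0.02), which did not pass adjustment (adjusted p = 0.0971). The IFNA set is small and its calls were not stable, which limits what its comparison can show.

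**Figure D5:**
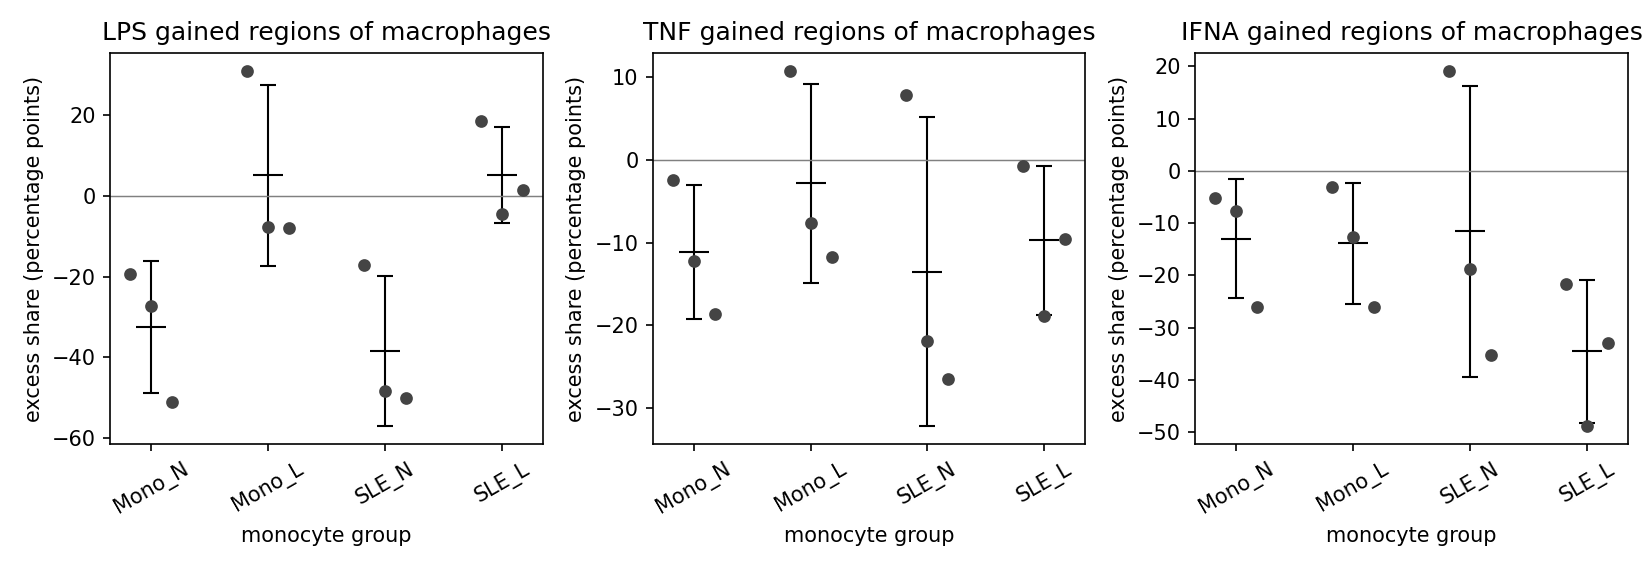
Excess share in percentage points (y axis, scaled separately in each panel) of the macrophage regions gained with LPS, TNF and IFNA, for each monocyte library by group (x axis); points are libraries, horizontal marks means and bars 1 SD, and the grey line marks 0. In the LPS panel the mean was 5.12 points in Mono_L and 5.19 in SLE_L, against -32.5 in Mono_N and -38.5 in SLE_N.

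Pairs of groups were also compared by the regions that separated them fully. LPS in naive macrophages separated 1819 regions held by all L and no N libraries and 659 of the reverse kind, 2478 in all, where the highest of the other splits drawn gave 2333. For 6 pairs of macrophage groups another split of the same libraries separated more regions: 3847 regions separated T and N against 4826 in another split, 1853 IFN and N against 4421, 3897 IFN_T and N against 4338, 1223 TL and L against 14644, and 4533 IFN_L and IFN against 7328, and 58 TL and T against 6172. IFN_TL held 13647 regions that no IFN_T library held and lacked 1901, and against TL it held 15224 and lacked 2525; the other splits gave at most 2241 and 1992 regions. IFN_TL held 1407 regions that no L library held and lacked 2166, 3573 in all, where the highest of the other splits gave 2540. With equal-length lists the balance turned: IFN_TL held 3383 and lacked 4435 against IFN_T, and held 4347 and lacked 6007 against TL. Over the 13647 regions a peak was also listed in 48.5% ± 24.4 of cases in N (SD, n = 5), against 2.41% ± 2.79 in T (SD, n = 3). In monocytes LPS separated 3599 and 781 regions, and another split of the same 6 libraries gave 9256. SLE_L and SLE_N were separated by 2691 and 2339 regions, with 8462 in another split. SLE_N and Mono_N were separated by 1610 and 1955 regions, with 10494 in another split. SLE_L and Mono_L were separated by 2064 and 3187 regions, 5251 in all, above the 4169 of the highest other split. Monocytes and naive macrophages, Mono_N against N, were separated by 1316 and 1777 regions, 3093 in all, with 2364 in the highest other split of 56. For pairs of 3 against 3 libraries only 10 splits exist, so these counts describe the libraries and carry no test.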

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

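The splits of the samples, the tests of the IFNA pattern on the IFN_TL libraries and of the IFN_TL batch, and the equal-length lists were chosen only after the result was seen. In 22 comparisons of single libraries with their group of 5, 1 stood apart: L replicate 2 covered 66.9 Mb, and chance gives about 1 in 20 such cases. Of 36 differences of responses between groups, 6 had an exact permutation p under 0.05. Over LPS gained regions the response after TNF was lower than the naive one by a difference of -52.7 points (exact permutation p = 0.00542), and over LPS lost regions it differed by 62.5 points (p = 0.00128). Over TNF gained regions the TNF response with IFNA differed from that without by -28.6 points (exact permutation p = 0.0143). Over regions called gained with TNF without IFNA libraries that difference was -53.9 points (exact permutation p = 0.00714). Over IFNA gained regions the LPS response with TNF and IFNA differed from that with TNF by -60.7 points (exact permutation p = 0.025). These 5 sets were called from the libraries compared, so their differences are not independent of the choice of regions, and how far the choice shaped them was not tested. The remaining set was chosen from monocytes: over regions lost with LPS there, the TNF response with IFNA differed from that without by -33.5 points (exact permutation p = 0.0357). The interaction values were not adjusted for the 36 computed.

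Chance was tested by 100 splits within strata, the real one included. The real split gave the highest count for each treatment and direction (1 of 100 splits gave as many). The highest other count was 0 against 243 for LPS gained, 0 against 453 for LPS lost, 86 against 2829 for TNF gained, 0 against 245 for TNF lost and 4 against 66 for IFNA gained regions. These counts exclude chance only for the main test and splits that ignore the replicate number. With that number as a block, LPS gained, LPS lost, TNF lost and IFNA gained regions numbered 0. The block leaves fewer arrangements, which limits how small p can become, so those 0 counts do not decide. For IFNA lost regions another split gave 159 against the real 168, so the margin there is narrow.

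More regions were gained than lost with TNF. Equal-length lists still gave 2.72 regions gained per region lost, although at an unadjusted p under 0.05 the excess was smaller, with 5352 gained and 3762 lost. After the cut, median peak width still ran from 627 to 1330 bp in T, 936 to 1805 bp in N and 1692 to 1908 bp in IFN_TL. The cut thus left the lists unequal, so it does not decide whether shorter TNF lists were the whole cause. The shortest lists alone are argued against by the ratio without them, 13.8. The better recovery of gains in simulated data, 190 against 87 of 200, stays open as part of the excess, and the biological explanation, an opening by TNF, remains a hypothesis.

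Regions lost with IFNA were mostly regions gained with TNF, which would be expected if IFNA kept TNF from opening them. Over the 168 regions IFN_T stood -72.8 points from T, but T and IFN_T helped to choose these regions, so this cannot exclude that the IFN_TL libraries drove the call. Over regions called gained with TNF without any IFNA library, the TNF difference with IFNA was lower by a value of -53.9 points; this was planned as decisive, but N and T chose those regions, so a smaller difference in other libraries does not decide. Over 2525 regions chosen from TL and IFN_TL only, IFN_T stood -18.9 points from T with no overlap of the libraries, short of the 20 points set in advance. That set, chosen without T and IFN_T, shows the same direction by less than the bound, so selection and an effect of IFNA cannot be told apart for the 168 regions.

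Peaks held by all IFN_TL and no IFN_T libraries numbered 13647. Longer lists may account for much of this: with equal-length lists the count was 3383, against 2305 for IFN_L and IFN. A difference in library or peak calling that untreated cells share is also consistent with the values, since N held 48.5% of these regions. A batch of the IFN_TL group is a candidate explanation too: its same-numbered libraries deviated with those of the other TNF or IFNA groups at a mean correlation of at most 0.07, where the lowest among the others was 0.162. Same-numbered N libraries deviated with those groups at only -0.03 to 0.024, however, so a low value is not particular to IFN_TL. An effect of the joint treatment was not separated from these.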

How the results depend on the processing

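Equal-length lists and the omission of the 4 shortest lists or the IFN_TL group were chosen after seeing the data. The planned gene list shares and motif counts were not run. Depth is unknown, and list length limits each count. Causes of the changes were not tested.

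Counts are gained then lost. Unweighted, LPS had 0 and 0 regions, TNF 75 and 39 and IFNA 0 and 0. With limma LPS had 1638 and 1396, TNF gained 1151, and IFNA 3 and 18. In 500-bp windows, which split regions into more units, LPS had 1048 and 2504, TNF 10099 and 989 and IFNA 339 and 723. With at least 6 libraries LPS had 380 and 833. With peaks covering at least 50% of the region LPS had 399 and 718 and IFNA gained 21. Equal-length lists gave 513 and 751 for LPS, 752 lost for TNF and 1 and 0 for IFNA (2949 and 2795 at an unadjusted p under 0.05). Without the 4 shortest lists LPS lost 273, TNF had 1253 and 91 and IFNA 0 and 0 (7531 and 3475 unadjusted). Without the IFN_TL group LPS had 74 and 77 and IFNA 0 and 0 (9953 and 2945 unadjusted). The other TNF counts stayed within 1.5 times.

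Replicate numbers paired 7 of 28 macrophage group pairs and 0 of 6 monocyte pairs (each same-number correlation over 0.1), and 20 of 28 macrophage libraries correlated best with their own number, so numbers pair part of the groups but were not taken to pair the set as a whole. With the replicate number as a block, LPS had 0 and 0 regions (3812 and 7914 unadjusted), TNF 489 and 0 (2982 lost unadjusted) and IFNA 0 and 27 (2736 gained unadjusted). The block leaves 16384 arrangements for LPS and 4096 each for TNF and IFNA, which limits how small p can become. The monocyte LPS set in naive macrophages no longer passed with the block (31.4 points, which the block leaves as it is by construction; exact permutation p = 0.0625, the smallest it allows).

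Leaving out each of 28 libraries gave 39 to 285 LPS gained, 32 to 689 LPS lost, 1923 to 3013 TNF gained, 112 to 255 TNF lost, 0 to 89 IFNA gained and 0 to 213 IFNA lost regions. LPS gained moved by over 1.5 times without N replicates 1 to 5 (129, 55, 65, 113 and 99), L replicates 1 to 5 (130, 79, 41, 95 and 94), IFN 1 and 2 (39 and 133) and IFN_L 1 to 3 (95, 116 and 148). LPS lost did so without N 1 to 5 (234, 154, 179, 116 and 245), L 3 to 5 (32, 124 and 122), T 3 (689), IFN 1 to 3 (193, 253 and 216) and IFN_L 1 to 3 (137, 271 and 230). TNF lost did so without T 1 and 2 (112 and 151) and TL 1 (139). IFNA gained did so without N 3 and 5 (25 and 28), L 3 to 5 (35, 36 and 35), T 1 (26), TL 2 and 3 (13 and 0), IFN 1 to 3 (40, 22 and 18), IFN_L 2 and 3 (26 and 31), IFN_T 3 (35) and IFN_TL 1 to 3 (21, 20 and 31). IFNA lost did so without T 3 (83), TL 2 and 3 (31 and 0) and IFN_TL 1 to 3 (52, 49 and 66).

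Among the set results, LPS in naive macrophages (27.1 to 35.1 points) and in monocytes over the macrophage set (34.2 to 46.0) kept their side of the test without each library. With covering peaks and with equal-length lists each set was chosen anew, so its regions differ from those of the main set. The lower LPS response after TNF ranged from -27.4 to -19.4 and passed without L replicate 4 (-27.4, exact permutation p = 0.0459), with covering peaks (-15.8) and with equal-length lists (-31.1). The effect of IFNA on it ranged from -9.65 to -5.07, passed without T replicate 3 (-9.65, exact permutation p = 0.03), and turned to 15.0 unmatched, 13.9 with covering peaks and 24.5 with equal-length lists. Neither SLE difference passed in any setting (-17.3 to -3.69 for IFNA and -10.0 to -1.24 for TNF without each library). Unmatched they were 2.02 and 0.39. Without SLE_N replicate 1 the IFNA difference of -17.3 lay at the bound (exact permutation p = 0.05). The IFNA set chosen anew held only 1 region with equal-length lists and 21 with covering peaks, so those settings show little about it.

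Fully separated regions with at most 1 exception in each group numbered 25662 and 4823 for Mono_L and Mono_N, 25324 and 24753 for SLE_L and SLE_N, 39744 and 11102 for SLE_N and Mono_N, 24743 and 16369 for SLE_L and Mono_L, and 5961 and 9891 for Mono_N and N. Equal-length lists gave 1146 for Mono_L, 1087 and 1042 for SLE_L and SLE_N, 214 for SLE_N against Mono_N, and 637 and 1463 for SLE_L and Mono_L.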

Other observations

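Regions that responded to one cytokine were described by how the other treatments left them. The 2829 regions gained with TNF were also more often held after LPS in naive macrophages, 36.4% ± 8.37 in L against 8.82% ± 5.73 in N (SD, n = 5 each), a difference in excess share of 24.1 points (exact permutation p = 0.0159). After IFNA, IFN_L differed from IFN by 21.8 points (exact permutation p = 0.1, the smallest possible). Over all strata the LPS difference was 7.09 points (permutation p = 0.163), and IFN_TL differed from IFN_T by -24.4 points (exact permutation p = 0.1, the smallest possible). Over regions called gained with TNF without IFNA libraries, the difference of L and N was 8.22 points (exact permutation p = 0.429). The 245 regions lost with TNF were held by 77.7% ± 6.36 of N (SD, n = 5), 87.8% ± 11.96 of IFN and 22.3% ± 18.4 of IFN_T (SD, n = 3 each). Of these regions 13 were also called gained with IFNA, where 0.09 were expected of independent lists; both calls use the same 28 libraries.

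Libraries of monocytes without SLE resembled each other more than those of SLE monocytes did. The mean Jaccard index of regions within a group was 0.708 in Mono_N and 0.651 in Mono_L, against 0.409 in SLE_N and 0.522 in SLE_L. List length varied more in SLE_N than in Mono_N, so the lower index is a value of these lists and was not tested.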
